A study of Mus musculus with 32 samples.

How the data were processed

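Nuclear RNA was sequenced from 32 sorted samples of mouse (C57BL/6, specific pathogen free) gut muscle layer and myenteric plexus: EGFP-positive and EGFP-negative nuclei, colon and small intestine, mice from Bern and from the Crick, with 4 libraries in each of the 8 groups. Per the labels' protocols, libraries were made with the NuGEN Ovation RNA-Seq V2 kit and read as single ends. The authors deposited 1 table of expected counts per Ensembl gene for the 32 libraries, which the column names mark as RSEM gene results. Per the submitters' processing notes the tools were RSEM 1.3.0, STAR 2.5.2 and DESeq2 1.10.1 with GRCm38, without a statement of their order or of the Ensembl release. The table holds 51912 gene identifiers with values in decimals and no common total, so it was treated as unscaled and rounded to whole counts. Library totals ran from 2394513 to 8350887 counts (median 4364112). A count of 0 in all 4 libraries of a group allows up to the floor of 3 counts over the group, which is 0.127 to 0.239 CPM. Symbols and GRCm38 coordinates were joined by identifier from GENCODE M21, which matched 51719 identifiers and left 193 without coordinates.

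The fits used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, a model of group means, the quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. The 10 comparisons were neuronal against non-neuronal nuclei over the 4 strata of facility and segment, colon against SI in neuronal nuclei over both facilities and in each, colon against SI in non-neuronal nuclei, Bern against Crick in neuronal nuclei of colon and of SI and in non-neuronal nuclei, and 2 interactions, segment by sort and segment by facility within neuronal nuclei. Neuronal and non-neuronal libraries were fitted apart (16 libraries each, 17419 and 19164 genes tested), except for the 2 comparisons across sorts, which used all 32 (21521 genes). SE of a fold change is its size divided by the square root of the test statistic. Groups, comparisons, lists, the rule for named genes and all alternatives not stated as added were fixed before the data were examined.

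Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted over 280 tests of lists with at least 2 tested genes. The 31 lists cover 12 cell types (neurons, glia, smooth muscle, interstitial cells of Cajal, fibroblasts with PDGFRA cells, macrophages with antigen presentation, lymphocytes, endothelium, epithelium, mesothelium, pancreatic acinar and erythroid cells), 3 neuron classes (cholinergic and tachykinin, nitrergic and VIP, sensory type), 4 sets of neuronal function (potassium channels, sodium and calcium channels, transmitter receptors, synaptic vesicle and release), 3 sets tied to microbes (aryl hydrocarbon receptor pathway, Toll-like and NOD receptors, interferon-stimulated genes), 2 Hox sets, 3 states (immediate early, circadian clock, heat shock), 2 measures of RNA quality (mitochondrially encoded and cytosolic ribosomal protein genes) and 2 checks of the animals (sex-linked genes and loci that differ between C57BL/6 substrains). The lists hold 389 different genes, of which 4 are in 2 lists: Snap25 and Syt1 (pan-neuronal and synaptic), Scn3a (pan-neuronal and channel) and Cacna1h (interstitial cells of Cajal and channel). Of the 280 tests 72 passed, and 24 of them also passed with the correlation estimated from the data: 13 in neuronal against non-neuronal nuclei (pan-neuronal, glia, smooth muscle, fibroblast, macrophage, endothelial, mesothelial, cholinergic, nitrergic, potassium channel, synaptic, Toll-like and NOD, Hox 9 to 13), 6 in the segment by sort interaction (pan-neuronal, interstitial cells of Cajal, macrophage, endothelial, Toll-like and NOD, Hox 9 to 13), the interstitial cells of Cajal in neuronal colon against SI over both facilities and in Crick, Hox 9 to 13 in non-neuronal colon against SI, and the pan-neuronal list in both neuronal facility comparisons. Median, mean and test differed in sign in 55 of the 280 tests, and among the tests that passed in 1, the mitochondrially encoded list of the non-neuronal facility comparison.

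In each comparison the rule named the 8 genes with the largest fold change in each direction among those past the threshold, with at least 5 CPM in the higher side and no overlap of libraries within each stratum. A few genes this rule selects are not reported here but stay in the counts. Genes with predicted symbols and members of lists for other cell types were counted, not named, and the condition on overlap could not be applied to the interactions. Chance separates 2.86% of genes in 1 stratum of 4 against 4 libraries, 0.0408% in 2 strata and 8.33e-06% in 4. Of the genes that met the conditions, those left unnamed as predicted or as markers of other cells numbered 229 of 1240 for neuronal against non-neuronal nuclei, 90 of 351, 107 of 517 and 36 of 157 for neuronal colon against SI over both facilities, in Bern and in Crick, 81 of 403 for non-neuronal colon against SI, and 78 of 416, 37 of 115 and 83 of 314 for the facility comparisons in colon neurons, SI neurons and non-neuronal nuclei. The rule added up to 4 members with the smallest p of each list that passed or held at least 3 genes past the threshold, and Ahr, Chat, Nos1, Vip and Nnt everywhere. The text prints these in order of size or of p and the rest as counts. Levels per group are given for Kit, Pou3f3, Egr1, Elavl4 and Myh11 as well, chosen after values were seen.

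The alternatives were DESeq2 size factors in edgeR, no filter except 1 count, DESeq2 1.42.0, limma-voom with sample quality weights, a block on the replicate number, all 32 libraries in 1 fit and leaving out each library. Chosen after seeing the data were the fit of each facility alone and the log2 Xist level as a covariate of the facility comparisons. So were fits without genes that mark neuronal nuclei and without the libraries in doubt. These were Crick_SiPos 2 and Crick_SiNeg 2 for their mitochondrial share and Bern_ColNeg 1 and 2 for neuronal transcripts in the EGFP-negative gate. Crick_ColNeg 3 was left out for its macrophage and lymphocyte sums. A further fit of the comparisons with non-neuronal nuclei also left out Bern_SiNeg 1. Neuronal comparisons left out Crick_SiPos 2 alone, and the one in Bern was not rerun. No library was left out of the reported fits.

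The steps were tested on simulated data with the means and spread of the real genes. For neuronal colon against SI edgeR recovered 13.4% of genes changed 2-fold, 68.7% of those changed 4-fold and 81.8% of those changed 8-fold, with 5.22% false calls, against 26.2% false calls for DESeq2 and 4.5% for limma-voom. In the single facility and single segment comparisons of neuronal nuclei 0% to 2.99% of 2-fold, 19.4% to 29.9% of 4-fold and 54.5% to 63.6% of 8-fold changes were recovered, so changes under 4-fold could mostly not be detected there. For the segment by facility interaction the shares were 0%, 2.99% and 28.8%. A simulated list of 20 rising genes passed camera with a p of 2.9e-50, and 1 of 100 random lists passed 0.05. Simulated genes were independent, so this cannot test the preset correlation. Of 144 groups of 4 values (each of the 8 groups in several measures and genes), 12 held a library beyond Dixon's critical value of 0.829. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.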

Results

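Nuclei were sorted from the muscle layer and myenteric plexus of mouse colon and small intestine (SI), 5 weeks after an intravenous adeno-associated virus had delivered EGFP tethered to the nuclear envelope under a CaMKII promoter. EGFP-positive nuclei are called neuronal and EGFP-negative nuclei non-neuronal, as in the labels. Mice came from 2 facilities, Bern and Crick, so facility, segment and sort made 8 groups of 4 libraries. Libraries are named by facility, segment (Col or Si), sort (Pos or Neg) and number. Total estimated counts ran from 2394513 to 4618395 in the 16 Bern libraries and from 3788206 to 8350887 in the 16 Crick libraries. A gene count above 0 was found for 15708 to 22533 genes per Bern library and 25789 to 35260 genes per Crick library. At an equal depth of 2394481 counts the ranges were 15125 to 21471 and 22971 to 31628 genes, which do not overlap. Mitochondrially encoded transcripts, which nuclei should largely lack, took 0.42% to 23.58% of the counts. The highest shares were in Crick_SiNeg 2 (23.58%, 95% Wilson interval 23.54% to 23.61%) and Crick_SiPos 2 (15.99%, 15.97% to 16.02%). In 5 libraries, chosen after seeing the data and called libraries in doubt, a list or share was high for the group: these 2, Bern_ColNeg 1 and 2 (pan-neuronal sums of 2130 and 1590 CPM, the upper end of a graded series with 1010 and 902 CPM) and Crick_ColNeg 3 (macrophage sum of 2630 CPM). Bern_SiNeg 1 stood apart, with a pan-neuronal sum of 894 CPM against 106 to 162 CPM in the rest of its group, and was left out with them in a further fit. Levels are given as CPM, counts scaled to a common library size, and fold changes as log2 ± SE from edgeR with its adjusted p. Intervals, errors of single shares and floors cover counting error only, since the reads carry no molecular identifiers.

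**Figure D1:**
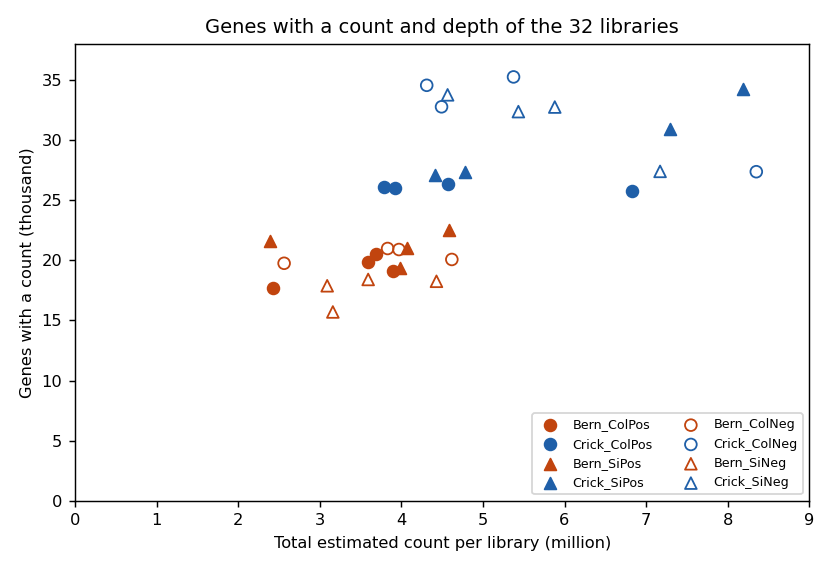
Number of genes with a count (vertical axis) against total estimated count (horizontal axis) for each of the 32 libraries, coloured by facility. Filled symbols are EGFP-positive and open symbols EGFP-negative nuclei, with circles for colon and triangles for SI. Every Crick library lies above every Bern library.

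The first question was which genes mark the nuclei in the EGFP-positive gate. All 20 genes of the pan-neuronal list rose in neuronal nuclei (20 adjusted over the list alone, median log2 fold change 3.60, list adjusted p = 5.66e-16). The neuronal intermediate filament gene Prph had a mean of 412 CPM in neuronal and 27.9 CPM in non-neuronal nuclei, a log2 fold change of 4.84 ± 0.29 (adjusted p = 3.43e-16, 16 libraries a side). Elavl4, a neuronal RNA-binding protein gene, rose by 3.96 ± 0.31 (2.49e-13). The summed level of the list was 3160 to 5720 CPM in the 4 neuronal groups and 187 to 1410 CPM in the 4 non-neuronal groups, where Bern colon was highest. Genes of transmitter classes rose too. All 7 members of the cholinergic and tachykinin list passed (7 adjusted over the list alone, list adjusted p = 2.76e-06), among them Chat, the enzyme of acetylcholine synthesis (4.14 ± 0.41, 8.78e-11), and Penk, the enkephalin precursor (4.36 ± 0.29). Of the 7 nitrergic and VIP genes 5 passed (6 adjusted over the list alone, list adjusted p = 0.000197), with Nos1, which makes nitric oxide, at 3.69 ± 0.36 (8.68e-11). The gene of vasoactive intestinal peptide, Vip, rose by 3.37 ± 0.38 (2.41e-09). Synaptic vesicle and release genes rose in 17 of 20 cases (17 adjusted over the list alone, list adjusted p = 1.54e-10), for instance Unc13a (4.54 ± 0.34).

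Ion channels and receptors moved mostly with the neurons. Among voltage-gated and inward-rectifier potassium channels 14 of 18 rose and 2 fell (15 and 2 adjusted over the list alone, list adjusted p = 1.29e-06), led by Kcnj6 (6.03 ± 0.42) and Kcnd2 (4.76 ± 0.29). Sodium and calcium channels gave 10 of 16 higher and 3 lower (10 and 3 adjusted over the list alone, list adjusted p = 0.00197, adjusted p = 0.188 with an estimated correlation), with Scn9a at 4.25 ± 0.27. Transmitter receptors gave 14 of 20 higher and 5 lower (14 and 5 adjusted over the list alone, list adjusted p = 0.000663, adjusted p = 0.125 with an estimated correlation), with the opioid receptor gene Oprm1 at 4.68 ± 0.29. Outside the lists the largest rises that separated all libraries within each facility and segment were Fibcd1 (6.57 ± 0.62), Tex50 (6.12 ± 0.61), Tmem132e (6.02 ± 0.70) and the receptor tyrosine kinase gene Ltk (5.83 ± 0.40). The gene of the aryl hydrocarbon receptor, Ahr, a ligand-activated transcription factor (chromosome 12, 35497974 to 35535038, GRCm38), did not pass (0.66 ± 0.32, adjusted p = 0.0984). Nnt, a mitochondrial transhydrogenase gene, fell by 2.07 ± 0.34 (4.35e-06).

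Genes of most other cell types fell in neuronal nuclei, although the pancreatic acinar and erythroid lists did not pass. All 12 smooth muscle genes fell (12 adjusted over the list alone, list adjusted p = 1.08e-13), including Smtn (-5.30 ± 0.24) and the smooth muscle myosin gene Myh11 (-4.36 ± 0.23). All 6 mesothelial genes fell (6 adjusted over the list alone, 2.63e-06), as did 8 of 9 enteric glia genes (8 adjusted over the list alone, 7.69e-05). Falls were also found for 10 of 13 fibroblast genes (11 adjusted over the list alone, 7.88e-09), 11 of 12 macrophage genes (11 adjusted over the list alone, 4.91e-07) and 10 of 11 endothelial genes (10 adjusted over the list alone, 1.51e-06). Epithelial genes fell in 11 of 13 cases (11 adjusted over the list alone, 2.69e-06, adjusted p = 0.188 with an estimated correlation), and the mucin gene Muc2 had 13.2 CPM in neuronal and 2630 CPM in non-neuronal nuclei. Lymphocyte genes fell in 5 of 9 cases (5 adjusted over the list alone, 0.00998, adjusted p = 0.327 with an estimated correlation). Toll-like and NOD receptor genes, sensors of microbial products, fell in 11 of 14 cases (1 higher and 11 lower adjusted over the list alone, 2.61e-05), with Nod1 at -4.87 ± 0.44. Mitochondrially encoded genes fell in 12 of 13 cases (13 adjusted over the list alone, 4e-05, adjusted p = 0.364 with an estimated correlation), mt-Nd4 by 2.23 ± 0.28. Among the 5 genes of interstitial cells of Cajal, the pacemaker cells of the gut, Etv1 rose by 2.03 ± 0.20. The others named here, Ano1 (-2.74 ± 0.32), Prkcq (-1.73 ± 0.38) and Kit (-1.52 ± 0.36) fell (1 higher and 3 lower adjusted over the list alone, list adjusted p = 0.703). These are averages over facility and segment on the log scale: in colon Kit averaged 7.71 and 6.83 CPM in Bern and Crick neuronal nuclei and 114 and 159 CPM in the non-neuronal ones. Its mean over all neuronal libraries, 177 CPM, exceeded the 145 CPM of the non-neuronal ones.

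In the test over 21521 genes, 9369 passed, 4723 higher and 4646 lower in neuronal nuclei. The Hox genes of paralogue groups 9 to 13 fell in 5 of 11 cases (5 adjusted over the list alone, list adjusted p = 7.12e-05). The call of Hoxa9 was lost without Bern_SiNeg 1 (adjusted p = 0.139), that of Hoxd11 without the same library (1) and that of Hoxd10 without Bern_SiNeg 4 or Crick_SiNeg 2 (1 in either case). Without the libraries in doubt and Bern_SiNeg 1 all 3 calls were lost (0.166 to 1) and 9203 genes passed.

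**Figure D2:**
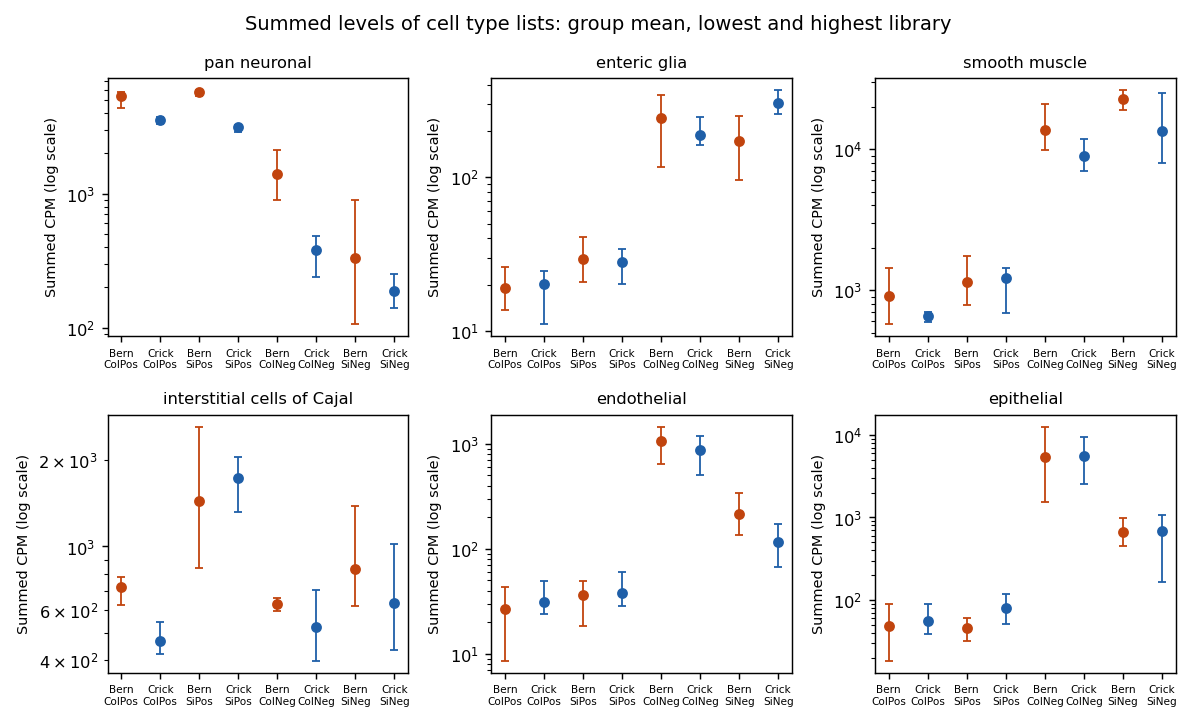
Summed level of 6 cell type lists (CPM, log axis) in each of the 8 groups, as the mean of 4 libraries with lines from the lowest to the highest library. Pan-neuronal sums are higher in EGFP-positive groups, and smooth muscle sums run the other way.

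The second question was how neurons of the colon differ from those of the SI. Ahr was 126 ± 47 CPM (SD, n = 4) in Bern colon neurons and 14 ± 12.5 CPM in Bern SI neurons, and 62.9 ± 10.9 against 9.11 ± 2.87 CPM in Crick neurons. Over both facilities Ahr rose in colon neurons by 2.93 ± 0.39 (adjusted p = 4.27e-05), and every colon library lay above every SI library within each facility. The largest rises were of Pantr2 (7.01 ± 0.72) and the neighbouring transcription factor gene Pou3f3 (chromosome 1, 42695768 to 42703176), at a mean of 110 CPM in colon and 0.944 CPM in SI neurons (6.97 ± 0.47, 2.25e-09). Next came the potassium channel gene Kcnk9 (6.11 ± 1.03), Kctd16 (5.67 ± 0.98), the synaptotagmin gene Syt10 (4.93 ± 0.71), Col25a1 (4.09 ± 0.33), Ano5 (3.30 ± 0.26) and Slc24a4 (3.23 ± 0.81, 0.0177). The enkephalin precursor gene Penk rose by 1.95 ± 0.25 (2.59e-05) and the substance P precursor gene Tac1 by 1.55 ± 0.23 (0.00016). The choline transporter gene Slc5a7 passed at -0.66 ± 0.20 (0.049) but lost the call (0.0614 to 0.132) without any library other than Bern_ColPos 4, Crick_ColPos 2 or Crick_SiPos 2. Nos1 (0.43 ± 0.19, adjusted p = 0.202), Vip (0.00 ± 0.38, 0.998), Chat (-0.53 ± 0.24, 0.231) and Nnt (-1.55 ± 0.56, 0.116) did not pass. In the cholinergic and tachykinin list 2 of 7 genes thus rose and 1 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.679), with a median log2 fold change of -0.31 but a mean of 0.21. The aryl hydrocarbon receptor pathway list had 1 of 7 genes higher, Ahr itself (2 adjusted over the list alone, list adjusted p = 0.149).

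Several groups fell in colon neurons. Of the 5 genes of interstitial cells of Cajal 4 fell (4 adjusted over the list alone, list adjusted p = 6.9e-08). Prkcq, a protein kinase C gene, was at -8.14 ± 0.56 (2.25e-09), the chloride channel gene Ano1 at -7.59 ± 0.55 and the receptor tyrosine kinase gene Kit (chromosome 5, 75574916 to 75656722) at -5.55 ± 0.60 (2.89e-06). Etv1 passed at -0.67 ± 0.18 (0.0313) but lost the call (0.0517 to 0.098) without Bern_ColPos 2, Bern_SiPos 1, Crick_ColPos 1, 3 or 4 or Crick_SiPos 1 or 2. Kit was 437 ± 90.8 CPM (356 to 567 CPM) in Crick SI neurons, with every library above those of the matching non-neuronal nuclei (122 ± 109 CPM, 47.5 to 283 CPM). In Bern the ranges overlapped, 255 ± 240 CPM in SI neurons (600 CPM in Bern_SiPos 1, 82.5 to 236 CPM in the others) and 184 ± 199 CPM in non-neuronal nuclei (478 CPM in Bern_SiNeg 1, 54.1 to 135 CPM in the others). Hox genes of paralogue groups 1 to 8, which set position along the body axis, fell in 6 of 19 cases (1 higher and 10 lower adjusted over the list alone, list adjusted p = 1.25e-05, adjusted p = 0.157 with an estimated correlation). Among them were Hoxc6 at -6.60 ± 0.93, Hoxc8 at -6.18 ± 1.01, Hoxc5 at -6.05 ± 1.00 and Hoxc4 at -2.39 ± 0.40. Only 1 gene of paralogue groups 9 to 13 had enough counts in neuronal nuclei to be tested. Outside the lists the largest falls included the endothelin gene Edn3 (-8.45 ± 1.01, 2.24e-05), Gpr20 (-7.94 ± 0.91), Adgrd1 (-7.57 ± 0.50) and the transcription factor gene Osr1 (-7.49 ± 0.65). In Bern SI neurons Edn3 and Gpr20 were highest in Bern_SiPos 1 (75.4 and 161 CPM), the library highest in Kit (600 CPM). Whether they share a source with Kit was not tested. Further down were the bile acid receptor gene Gpbar1 (-7.33 ± 0.88) and the cadherin gene Cdh9 (-6.64 ± 0.71). Mitochondrially encoded genes fell in 10 of 13 cases beside these (12 adjusted over the list alone, list adjusted p = 1.08e-13, adjusted p = 0.148 with an estimated correlation), mt-Nd4 by 3.53 ± 0.42 and mt-Cytb by 3.39 ± 0.38. The mitochondrial share did not overlap in Bern (colon 0.42% to 0.6%, SI 2.75% to 6.82%) or Crick (0.83% to 1.39%, 2.76% to 15.99%). SI libraries thus held more RNA that nuclei should largely lack. Whether it adds to the other falls was not tested. Smooth muscle genes fell in 3 of 12 cases (1 higher and 3 lower adjusted over the list alone, list adjusted p = 0.101), with Smtn at -1.88 ± 0.36 and Mylk at -1.57 ± 0.27. Myh11 passed at -1.04 ± 0.27 but lost the call (0.0522 to 0.0606) without Bern_SiPos 1 or 3, Crick_ColPos 2 or Crick_SiPos 1 or 2. The sodium and calcium channel list passed with 1 of 16 genes lower, Cacna1g at -2.60 ± 0.54 (3 adjusted over the list alone, list adjusted p = 0.0441, adjusted p = 0.364 with an estimated correlation). It lost the call without any of 9 libraries (unadjusted list p of 0.0134 to 0.0452): Bern_ColPos 1, 2 and 3, Bern_SiPos 1, 2 and 4, Crick_ColPos 1 and 2 and Crick_SiPos 2. Over both facilities 960 of 17419 genes passed, 343 higher and 617 lower in colon neurons. The number was 1905 with DESeq2 and 1652 without a filter on low counts, and Slc24a4 lost its call with all 32 libraries in 1 fit (0.0563).

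**Figure D3:**
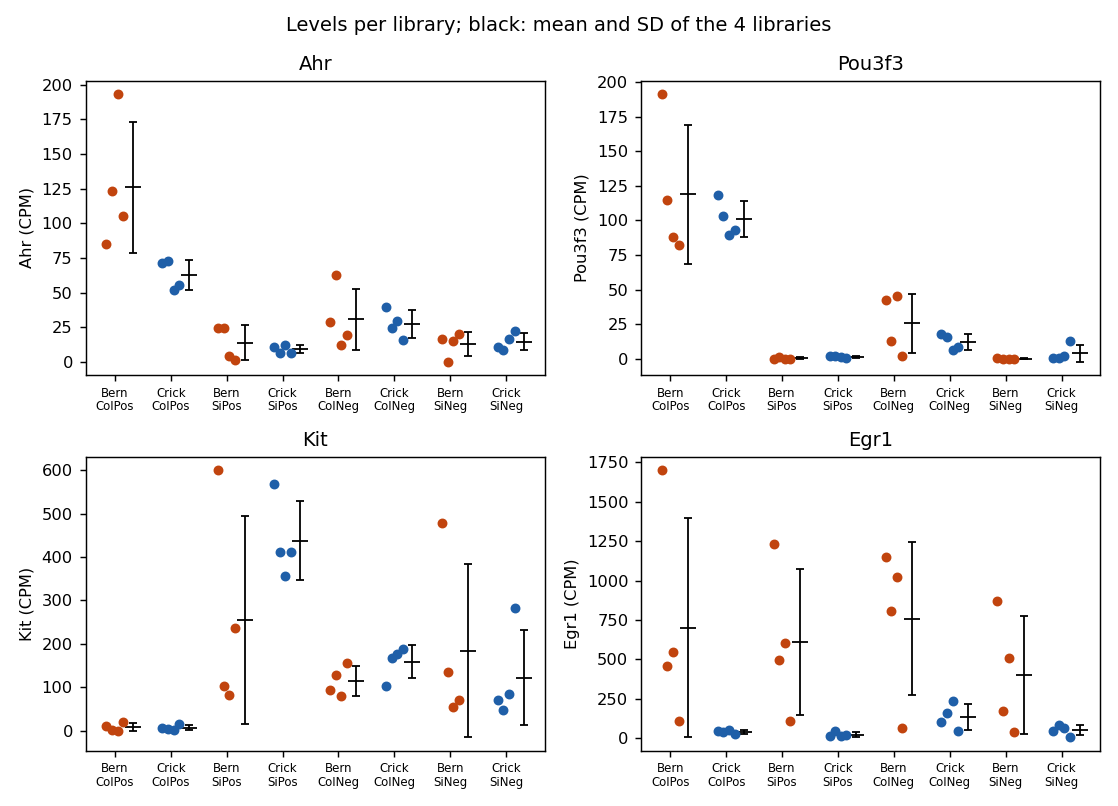
Level (CPM) of Ahr, Pou3f3, Kit and Egr1 in each of the 32 libraries by group, with the group mean and SD (n = 4). Ahr is higher in colon than in SI neurons, and Egr1 in Bern than in Crick neurons.

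Each facility was also asked alone, with its own 8 libraries compared within the fit of all 16. In Bern, Pou3f3 rose by 7.91 ± 0.71 (adjusted p = 1.11e-06), Ahr by 3.12 ± 0.56 (0.00273) and Penk by 2.25 ± 0.36 (0.000937), and Ano1 (-8.82 ± 0.84), Prkcq (-8.86 ± 0.85) and Kit (-5.09 ± 0.84) fell. Some genes had no count in any of the 4 Bern SI libraries: Kctd16 (20.8 ± 35.9 CPM) was at least 101-fold and Kcnk9 (8.04 ± 5.11 CPM) at least 38.9-fold higher in Bern colon neurons, against a floor of 3 counts over the group. Without Bern_ColPos 3 the bound for Kctd16 is 13.8-fold. With no count in Bern colon neurons, Gpr20 (65 ± 65.8 CPM in SI) was at least 314-fold, Edn3 (28.6 ± 34.8) at least 138-fold, Cdh9 (19.2 ± 14.4) at least 92.9-fold and Capn12 (14.8 ± 14.9) at least 71.5-fold lower. Smad7 (10.1 ± 10.9) was at least 48.8-fold and Rcn3 (10 ± 10.5) at least 48.4-fold lower. These bounds fall to 159, 62.5, 59.6 and 41.1 without Bern_SiPos 1, to 25.2 for Smad7 without Bern_SiPos 2 and to 32.1 for Rcn3 without Bern_SiPos 3. With limma-voom the calls of these genes other than Gpr20 and Cdh9, and that of Prkcq, were lost in Bern (adjusted p of 0.0538 to 0.262). In Crick, Pantr2 (6.51 ± 0.96) and Pou3f3 (6.02 ± 0.62, adjusted p = 5.91e-06) rose most, followed by Col25a1 (4.02 ± 0.46), the phosphodiesterase gene Pde1c (3.25 ± 0.28), the guidance gene Sema3e (3.07 ± 0.60) and Ano5 (2.96 ± 0.36). Ahr rose by 2.75 ± 0.55 (0.0113), a call lost without Crick_SiPos 2 (0.0544) or 4 (0.0557). Wnk4 rose by 3.36 ± 0.71 (0.0171) but lost the call without Crick_ColPos 4 (0.151) or Crick_SiPos 1 (0.0868), 3 (0.0581) or 4 (0.0769). Osr1 (-8.12 ± 0.96), Pde4c (-7.58 ± 0.84), Hoxc6 (-7.45 ± 1.35), Prkcq (-7.42 ± 0.72), Ano1 (-6.36 ± 0.69) and Kit (-6.02 ± 0.87) fell, and Gpbar1, without a count in Crick colon neurons, was at least 45.9-fold lower.

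The genes of interstitial cells of Cajal fell in 3 of 5 cases in either facility (3 in Bern and 4 in Crick adjusted over the list alone, list adjusted p = 7.15e-05 in Bern, with adjusted p = 0.147 with an estimated correlation, and 2.12e-11 in Crick). Mitochondrially encoded genes fell in 9 of 13 cases in Bern and 8 in Crick (10 and 12 adjusted over the list alone, 2.7e-09 and 1.38e-15, adjusted p = 0.237 and 0.125 with an estimated correlation). For the Hox genes of groups 1 to 8 the numbers were 5 and 2 of 19 (8 lower with 1 higher in Bern and 5 lower in Crick adjusted over the list alone, 0.00272 and 3.69e-07, adjusted p = 0.327 and 0.103 with an estimated correlation). In Crick the smooth muscle list passed with 1 of 12 genes lower (3 adjusted over the list alone, 0.00239, adjusted p = 0.36 with an estimated correlation). The Toll-like and NOD receptor list passed with no gene past the threshold (0 adjusted over the list alone, 0.0331, adjusted p = 0.147 with an estimated correlation) and not without Crick_ColPos 3 or 4 or Crick_SiPos 3 (unadjusted list p of 0.0117 to 0.0195).

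In Bern 727 genes passed, 228 higher and 499 lower, and in Crick 159, 58 higher and 101 lower. Which facility has more genes depends on the fit, as limma-voom gave 51 in Bern and 2152 in Crick, and the 8 libraries of each facility alone gave 101 and 540. Of the higher genes 37 were shared where chance gives 0.759 (Fisher's exact test, one-sided p = 2.67e-56), of the lower ones 80 where chance gives 2.89 (p = 8.45e-106), and 0 were opposite. The Bern count fell to 433 without Bern_SiPos 4, and the Crick count to 92, 91 and 96 without Crick_ColPos 1, 2 and 3 and to 97 and 93 without Crick_SiPos 1 and 2. The test of the difference between the facilities passed for 1 gene only, ENSMUSG00000092267 (adjusted p = 0.00716), which has no entry in the annotation used here. It averaged 468 ± 334 CPM (SD, n = 4) in Bern colon neurons and 0.313 ± 0.626 CPM in Crick SI neurons, and had no count in the other 2 groups. It lost the call without Crick_SiPos 4 (adjusted p = 1) and with all 32 libraries in 1 fit (0.424). With edgeR 1134 of 17419 genes had an unadjusted p under 0.05 in this test, DESeq2 passed 47 genes and limma-voom 4. Without Bern_ColPos 1 or 2 the edgeR count was 3 or 2, and without Crick_SiPos 4 it was 0. For Ahr the difference was 0.37 ± 0.74 (0.942), for Nos1 0.34 ± 0.37 (0.888), for Chat -0.68 ± 0.48 (0.822), for Vip -1.93 ± 0.80 (0.719) and for Nnt -1.69 ± 1.1 (0.815). The fibroblast list alone passed in this test, with 0 of 12 genes past the threshold (0 adjusted over the list alone, list adjusted p = 0.0372, adjusted p = 0.211 with an estimated correlation). It lost the call without any of 9 libraries (unadjusted list p of 0.0114 to 0.0542): Bern_ColPos 1 and 4, Bern_SiPos 2 and 4, Crick_ColPos 3 and 4 and Crick_SiPos 1, 2 and 3.

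Non-neuronal nuclei of colon and SI were compared to see which segment differences lie outside the EGFP-positive gate. All 11 tested Hox genes of paralogue groups 9 to 13, the posterior members of the family, rose in colon (11 adjusted over the list alone, median log2 fold change 6.78, list adjusted p = 1.28e-15). Hoxa10 rose by 8.27 ± 1.09 (0.00011), Hoxa13 by 8.06 ± 0.99 (5.71e-05), Hoxd10 by 7.15 ± 0.95 and Hoxd9 by 6.85 ± 0.94. In the groups 1 to 8, Hoxd4 (4.53 ± 0.93) and Hoxd8 (4.18 ± 0.86) rose and 4 of 21 fell, Hoxc6 by 3.63 ± 0.64 (2 higher and 5 lower adjusted over the list alone, list adjusted p = 0.0127, adjusted p = 0.196 with an estimated correlation). Endothelial genes rose in 8 of 11 cases (8 adjusted over the list alone, list adjusted p = 2.95e-07, adjusted p = 0.0604 with an estimated correlation), among them the lymphatic markers Flt4 (5.84 ± 0.47, 6.49e-08), Prox1 (4.29 ± 0.56) and Lyve1 (3.73 ± 0.48). Epithelial genes rose in 5 of 13 cases and fell in 1, Fabp2 (9 and 1 adjusted over the list alone, 0.00279, adjusted p = 0.476 with an estimated correlation), with Muc2 at 4870 CPM in colon and 396 CPM in SI (3.54 ± 0.44). Macrophage genes rose in 3 of 12 cases (6 adjusted over the list alone, 0.0068, adjusted p = 0.158 with an estimated correlation), Cd74 by 2.52 ± 0.54.

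Neuronal genes also rose in the non-neuronal colon nuclei. Of the pan-neuronal list 9 of 20 passed (15 higher and 1 lower adjusted over the list alone, list adjusted p = 6.13e-11, adjusted p = 0.083 with an estimated correlation), with Phox2a at 5.08 ± 1.06 and Prph at 2.87 ± 0.52. The summed level of that list was 1410 ± 568 CPM in Bern colon against 331 ± 376 CPM in Bern SI (SD, n = 4), where Bern_SiNeg 1 held 894 CPM and the other libraries 106 to 162 CPM, and 383 ± 108 against 187 ± 56.1 CPM in Crick. Transmitter receptors rose in 10 of 19 cases and fell in 1 (13 and 1 adjusted over the list alone, 0.000663, adjusted p = 0.187 with an estimated correlation). Synaptic vesicle genes rose in 6 of 19 cases (9 adjusted over the list alone, 0.00111, adjusted p = 0.237 with an estimated correlation). Nitrergic and VIP genes rose in 3 of 5 (3 adjusted over the list alone, 0.0107, adjusted p = 0.235 with an estimated correlation). Vip rose by 2.92 ± 0.65 (0.00698), Nos1 by 2.37 ± 0.61 (0.0164) and Penk by 2.77 ± 0.68. Chat (2.32 ± 0.81, 0.0737), Ahr (0.99 ± 0.54, 0.271) and Nnt (-0.90 ± 0.37, 0.126) did not pass. The cholinergic and tachykinin list had 2 of 7 genes higher (3 higher and 1 lower adjusted over the list alone, 0.0214, adjusted p = 0.364 with an estimated correlation, lost without Bern_SiNeg 2 at an unadjusted list p of 0.0147).

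Falls in colon included muscle genes. Smooth muscle genes fell in 4 of 12 cases (1 higher and 6 lower adjusted over the list alone, list adjusted p = 0.00198, adjusted p = 0.451 with an estimated correlation). Examples are Mylk, the myosin light chain kinase gene (-1.39 ± 0.22), and Myocd (-1.67 ± 0.37). Myh11 (-0.99 ± 0.27, 0.0237) and Lmod1 (-1.29 ± 0.34, 0.0183) lost their calls without Crick_ColNeg 1 (0.056 and 0.0541), Crick_ColNeg 3 (0.0523 and 0.0509) or Crick_SiNeg 2 (0.0588 and 0.0717). The largest falls were of Sctr, the secretin receptor gene (-7.45 ± 0.69, 5.21e-07), the cation channel gene Hcn4 (-6.94 ± 0.58, 9.83e-08), the glutamate receptor gene Grm8 (-5.73 ± 0.61), Esrrb (-5.49 ± 1.05), Ltbp2 (-5.35 ± 0.58), Col6a4 (-5.25 ± 0.83) and Cyp1b1 (-5.02 ± 0.86). Fibroblast genes fell in 4 of 13 cases, Pdgfra by 1.49 ± 0.28, and Pi16 rose by 3.52 ± 0.77 (1 higher and 5 lower adjusted over the list alone, 0.0203, adjusted p = 0.158 with an estimated correlation). Without Bern_ColNeg 2 or Bern_SiNeg 3 the list lost its call (unadjusted list p of 0.013 and 0.0117). Of the mesothelial list Upk1b fell by 2.60 ± 0.63 (4 adjusted over the list alone, 0.0151, adjusted p = 0.114 with an estimated correlation). Mitochondrially encoded genes fell in 10 of 13 cases (10 adjusted over the list alone, 1.54e-07, adjusted p = 0.3 with an estimated correlation), mt-Nd4 by 1.80 ± 0.34. Cytosolic ribosomal protein genes rose in 3 of 20 (4 adjusted over the list alone, 0.00216, adjusted p = 0.406 with an estimated correlation). In all 1787 of 19164 genes passed, 1109 higher and 678 lower in colon. Without the 4 libraries in doubt the calls of Pi16, Nos1, Upk1b, Myocd, Vip, Cd74, Penk, Esrrb and Prph were lost (0.0571 to 0.222), those of Cd74 and Upk1b also with limma-voom (0.196 and 0.0828). With Bern_SiNeg 1 left out as well, those of Pi16, Vip, Penk, Upk1b, Myh11 and Lmod1 were lost (0.0515 to 0.279) and Chat passed (4.48, 0.0107). The count was 1172 without Crick_SiNeg 1, 377 without the 4 libraries in doubt, 764 without these and Bern_SiNeg 1, 1051 without the genes that mark neuronal nuclei, 3190 with DESeq2 and 1178 with limma-voom.

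Whether the segment difference itself differs between neuronal and non-neuronal nuclei was tested as an interaction, where the median over all genes was -0.224 and each value is to be read against it. The genes of interstitial cells of Cajal fell far more in colon neurons than in the surrounding nuclei, by 7.73 ± 0.79 for Prkcq (2.95e-08), 6.92 ± 0.66 for Ano1 (8.2e-09) and 5.36 ± 0.76 for Kit (1.86e-05). Of the list 3 of 5 were past the threshold (4 adjusted over the list alone, list adjusted p = 1.24e-06). Endothelial genes were lower in this contrast in 7 of 11 cases (7 adjusted over the list alone, 2.46e-07), with Prox1 at -7.82 ± 0.88 and Lyve1 at -6.27 ± 0.68. Pan-neuronal genes were lower in 10 of 20 (1 higher and 16 lower adjusted over the list alone, 1.14e-11), with Phox2a at -5.06 ± 0.88, Prph at -2.79 ± 0.52 and Elavl4 at -2.39 ± 0.56. The summed list differed little between colon and SI neurons (5420 and 5720 CPM in Bern, 3560 and 3160 CPM in Crick). In non-neuronal nuclei it was higher in colon (above). The lower values of this list thus reflect neuronal transcripts in non-neuronal colon nuclei and show no loss in colon neurons. Chat and Vip, below, did not pass between colon and SI neurons either. Hox genes of groups 9 to 13 were lower in 2 of 11 cases (3 adjusted over the list alone, 4.17e-12). The same held for macrophage genes in 4 of 12 (7 adjusted over the list alone, 0.000737, Ptprc at -5.00 ± 0.92) and Toll-like and NOD receptors in 1 of 14 (2 adjusted over the list alone, 0.00236). Grm8, Hcn4 and Sctr, which fell in non-neuronal colon nuclei, were higher in the contrast, at 7.96 ± 0.82 (2.95e-08), 6.15 ± 1.1 (0.000554) and 5.28 ± 0.82 (8.23e-05). Chat (-2.83 ± 0.74, 0.0164) and Vip (-2.96 ± 0.72, 0.0101) were lower, calls lost without the 5 libraries in doubt (0.0635 and 0.0597) but not with Bern_SiNeg 1 left out as well, while Nos1 (-1.92 ± 0.66, 0.0715), Ahr (1.91 ± 0.65, 0.068) and Nnt (-0.66 ± 0.66, 0.658) did not pass. Nos1 passed without these 5 libraries and Bern_SiNeg 1 (-2.83, 6.87e-06). Further down, Pkhd1 (-10.19 ± 1.79), Ackr2 (-10.05 ± 1.72), Cdh9 (-8.09 ± 1.54) and Fut4 (-7.93 ± 1.66) were among the lowest values, and the call of Pkhd1 was lost without Bern_SiPos 4 (adjusted p = 1). With limma-voom the calls of Vip, Prph, Ptprc and Pkhd1 were lost (0.0704 to 0.308).

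The other lists that passed in this contrast lost the call with an estimated correlation. They were transmitter receptors (11 of 20 lower and 1 higher, 14 and 1 adjusted over the list alone, 4.91e-05, adjusted p = 0.0586 with an estimated correlation) and epithelial genes (2 of 13 lower, 4 adjusted over the list alone, 0.000589, adjusted p = 0.36 with an estimated correlation). Synaptic vesicle genes were among them too (5 of 20 lower, 9 lower and 1 higher adjusted over the list alone, 0.00177, adjusted p = 0.172 with an estimated correlation). Mitochondrially encoded genes (4 of 13 lower, 10 adjusted over the list alone, 0.00144, adjusted p = 0.476 with an estimated correlation) did so too, with the call of mt-Nd1 (-1.89 ± 0.50) lost without Crick_SiPos 2 (0.0585). The nitrergic and VIP list (2 of 7 lower, 3 adjusted over the list alone, 0.0144, adjusted p = 0.188 with an estimated correlation) lost its call without Bern_SiNeg 4 as well (unadjusted list p = 0.0159). The cholinergic and tachykinin list (1 of 7 lower, 1 adjusted over the list alone, 0.0343, adjusted p = 0.364 with an estimated correlation) lost it without any of 9 libraries (unadjusted list p of 0.0115 to 0.0277): Bern_ColNeg 1 and 3, Bern_SiNeg 2, 3 and 4, Crick_ColNeg 2 and Crick_SiNeg 1, 2 and 3. The contrast passed for 1395 of 21521 genes, 235 higher and 1160 lower, and for 648 without the 5 libraries in doubt, 1137 without these and Bern_SiNeg 1, 661 without the genes that mark neuronal nuclei, 2286 with DESeq2 and 858 with limma-voom. Neuronal and non-neuronal nuclei shared 75 of their genes higher in colon (295 and 743 among genes tested in both) where chance gives 13.7, and 125 of those lower (579 and 585) where chance gives 21.2 (Fisher's exact test, one-sided p = 5.63e-35 and 2.48e-62). A further 8 genes were higher in colon in neuronal and lower in non-neuronal nuclei, and 16 the other way round. The p-values of the overlap take the sorts as independent, which was not shown. Libraries with the same number have the same sex markers, and non-neuronal colon nuclei held neuronal transcripts.

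The facility comparison asked whether neurons of mice kept in Bern differ from those kept at the Crick. In colon neurons Egr1, an immediate early transcription factor gene (chromosome 18, 34859823 to 34864984), was 702 ± 692 CPM in Bern and 39.2 ± 12.4 CPM at the Crick (SD, n = 4). It was higher by 4.15 ± 0.70 (adjusted p = 0.00542) with every Bern library above every Crick library. The immediate early list had 2 of 13 genes higher in Bern (3 adjusted over the list alone, list adjusted p = 0.00145, adjusted p = 0.364 with an estimated correlation). Of the pan-neuronal list 2 of 20 genes rose (5 adjusted over the list alone, 2.3e-05): Snap25, a gene of the vesicle fusion machinery, by 0.93 ± 0.23 (0.0329), and Ret, the receptor of glial cell line-derived neurotrophic factor, by 0.96 ± 0.21 (0.0208). The summed pan-neuronal level was 5420 ± 697 CPM in Bern and 3560 ± 173 CPM in Crick colon neurons. The mitochondrial share differed too, lower in every Bern than in any Crick library (above). Next to Egr1 the largest rises were of Adat3 (3.87 ± 0.73, 0.00858) and Foxp4 (3.82 ± 0.90, 0.0263), and the largest falls of the olfactory marker gene Omp (-5.69 ± 1.35, 0.0267), Swap70 (-5.14 ± 1.06, 0.0147) and Zscan12 (-4.77 ± 0.86, 0.00704). Synaptic vesicle genes gave 3 of 20 higher, with Syn1 at 1.82 ± 0.34 (0.00858), and 1 lower, Rims2 (3 and 1 adjusted over the list alone, list adjusted p = 0.0648). Nos1 (0.86 ± 0.27, 0.0697), Ahr (0.99 ± 0.52, 0.283), Vip (0.27 ± 0.56, 0.825), Chat (0.17 ± 0.34, 0.817) and Nnt (-0.92 ± 0.79, 0.537) did not pass. In colon neurons 538 of 17419 genes passed, 330 higher and 208 lower in Bern.

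Single libraries moved these colon calls. The count was 289 without Bern_ColPos 1, 1149 without Bern_ColPos 4, and 82, 59 and 133 without Crick_ColPos 1, 2 and 3. Of the 22 named genes that passed, 3 kept the call with any library left out: Egr1, Swap70 and Zscan12. Without Crick_ColPos 2 the adjusted p was 0.0513 for Adat3 and 0.0501 for Syn1. Ret lost its call without Crick_ColPos 1, 2 or 3 (0.0834, 0.0876 and 0.0585), Foxp4 without Bern_ColPos 3 (0.149) or Crick_ColPos 1, 2 or 3 (0.107, 0.106 and 0.0759) and Omp without Bern_ColPos 1 or 3 or Crick_ColPos 1, 2 or 4 (0.0557 to 0.0842). Rims2 lost it without Bern_ColPos 1 or 3 or Crick_ColPos 1, 2 or 3 (0.0596 to 0.108) and Snap25 without any library other than Bern_ColPos 1 or 4 (0.0529 to 0.104). With the 32 libraries in 1 fit the calls of Adat3, Syn1, Ret, Snap25, Rims2 and Omp were lost (0.0527 to 0.446) and the count was 164, with Xist as a covariate 307, with DESeq2 1777 and with limma-voom 1307.

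In SI neurons Egr1 was 609 ± 463 CPM in Bern and 22.2 ± 15.8 CPM at the Crick, a rise of 4.74 ± 0.72 (adjusted p = 0.0029). The immediate early list had 1 of 13 genes higher (6 adjusted over the list alone, list adjusted p = 8.29e-06, adjusted p = 0.232 with an estimated correlation). Snap25 rose from 529 to 2000 CPM (1.91 ± 0.24, 0.000284) and Sync, which encodes an intermediate filament protein, by 2.43 ± 0.33 (0.0008). With Stmn2 (1.37 ± 0.30, 0.0329) that made 2 of 20 pan-neuronal genes higher (5 adjusted over the list alone, list adjusted p = 3.37e-06), and the summed level of the list was 5720 ± 230 against 3160 ± 173 CPM. The largest change upward was of the pseudogene Mid1-ps1 (5.72 ± 1.12, 0.0179), and the largest downward were of the intermediate filament gene Nes (-6.24 ± 1.47, 0.0471), the cholesterol transporter gene Npc1l1 (-5.33 ± 1.08, 0.0227) and the apolipoprotein gene Apob (-3.22 ± 0.72, 0.0394). Beside them the epithelial list was lower with 0 of 8 genes past the threshold (3 adjusted over the list alone, 0.0068, adjusted p = 0.128 with an estimated correlation). The cholinergic and tachykinin list was higher with 0 of 7 past it (3 adjusted over the list alone, 0.00216, adjusted p = 0.129 with an estimated correlation). Vip (2.20 ± 0.58, 0.0894), Chat (0.84 ± 0.34, 0.324), Nnt (0.76 ± 0.77, 0.788), Ahr (0.62 ± 0.53, 0.733) and Nos1 (0.53 ± 0.26, 0.466) did not pass. In SI neurons 119 of 17419 genes passed, 99 higher and 20 lower in Bern, and 1960 had an unadjusted p under 0.05.

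Here too single libraries decided calls. The count was 41, 44 and 65 without Bern_SiPos 1, 2 and 3, and 11, 78, 27 and 24 without Crick_SiPos 1, 2, 3 and 4. Egr1, Sync and Snap25 kept their calls with any library left out. Mid1-ps1 lost its call without Crick_SiPos 1, 3 or 4 (adjusted p = 0.0906, 0.0785 and 0.065) and Nes without any of the 8 libraries (0.0601 to 0.153). Npc1l1 lost it without Bern_SiPos 1, 2 or 3 or Crick_SiPos 1 or 2 (0.0581 to 0.109), and Stmn2 (0.0606 to 0.116) and Apob (0.052 to 0.169) without any library other than Bern_SiPos 4. Of the remaining lists, the synaptic vesicle list passed with 2 of 20 genes higher (3 adjusted over the list alone, 0.0235, adjusted p = 0.103 with an estimated correlation) and not without Bern_SiPos 2 (unadjusted list p = 0.0132). The nitrergic and VIP list, with 0 of 6 past (2 adjusted over the list alone, 0.0331, adjusted p = 0.147 with an estimated correlation), did not pass without Bern_SiPos 2 (unadjusted list p = 0.0136), Bern_SiPos 4 (0.0126) or Crick_SiPos 4 (0.0168). The potassium channel list, with 1 of 17 genes higher (2 adjusted over the list alone, 0.0375, adjusted p = 0.172 with an estimated correlation), did not pass without Bern_SiPos 2, 3 or 4 (unadjusted list p = 0.0204, 0.0209 and 0.0553) or Crick_SiPos 3 or 4 (0.016 and 0.0279). The Toll-like and NOD receptor list was lower with 0 of 5 past (0 adjusted over the list alone, 0.039, adjusted p = 0.157 with an estimated correlation) and did not pass without Bern_SiPos 1 or 3 (unadjusted list p = 0.0608 and 0.019) or Crick_SiPos 2 (0.0309). With the 32 libraries in 1 fit Snap25 (0.206) and Mid1-ps1 (0.111) lost their calls. The count was 43 with that fit, 68 with Xist as a covariate, 447 with DESeq2 and 677 with limma-voom.

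Colon and SI neurons shared 56 genes higher in Bern (330 and 99) where chance gives 1.88 (Fisher's exact test, one-sided p = 2.96e-71) and 10 genes lower (208 and 20) where chance gives 0.239 (p = 7.9e-15). With the non-neuronal nuclei included, 45 genes were higher and 8 lower in Bern in all 3 facility comparisons. These are not to be read as independent repeats, since libraries with the same number have the same sex markers, and Egr1 runs from high to low in the order 1, 3, 2, 4 in all 4 Bern groups.

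In non-neuronal nuclei over both segments, Egr1 rose in Bern by 2.74 ± 0.56 (adjusted p = 0.00362) and the phosphatase gene Dusp1 by 1.73 ± 0.29 (0.000938), and Atf3 fell by 3.30 ± 0.82. The immediate early list had 3 of 14 genes higher and 1 lower there (4 and 1 adjusted over the list alone, list adjusted p = 0.162). The call of its member Npas4 (1.23 ± 0.37, 0.0413) was lost (0.0511 to 0.114) without Bern_ColNeg 1 or 3, Crick_ColNeg 1 or 3 or Crick_SiNeg 1, 3 or 4. The zinc finger genes Zfp935 (7.66 ± 1.03, 0.000204) and Zfp612 (2.38 ± 0.23, 3.08e-06), Optc (2.76 ± 0.31) and Nab2, which encodes a corepressor of Egr1 (2.55 ± 0.47), were among those that rose most. So were Serac1 (2.50 ± 0.42), Tmem252 (2.46 ± 0.28) and the clock gene Per1 (2.29 ± 0.27, 2.23e-05), with every Bern library above every Crick library in each segment. The genes Tnfrsf13c, Fcmr and Cd79b, which B cells express, had no count in the 8 Bern libraries: against a floor of 3 counts over them, Tnfrsf13c (20.1 ± 49 CPM in Crick, SD, n = 8) was at least 191-fold, Fcmr (15.3 ± 35.6) at least 146-fold and Cd79b (13.7 ± 31.5) at least 130-fold lower. Most of this comes from Crick_ColNeg 3, without which the bounds are 26.8, 26.4 and 24.6. The olfactory receptor gene Olfr295 (6.3 ± 3.48) was at least 59.9-fold lower. Lymphocyte genes fell in 4 of 9 cases (6 adjusted over the list alone, list adjusted p = 0.00817, adjusted p = 0.364 with an estimated correlation). Cd3e, a T cell gene (-3.32 ± 0.90), lost its call without Crick_ColNeg 4 (0.0544). The summed lymphocyte level was 295 ± 371 CPM in Crick_ColNeg, where library 3 alone held 846 CPM, against 86.1 ± 59.3 CPM in Bern_ColNeg. In SI it ran the other way, 184 ± 131 CPM in Bern and 120 ± 80.6 CPM in Crick. Smooth muscle genes rose in 3 of 12 cases (6 adjusted over the list alone, 1.92e-08, adjusted p = 0.176 with an estimated correlation): Tpm2 by 0.93 ± 0.25, Myh11 by 0.88 ± 0.27 and Des by 0.67 ± 0.21. The calls of Myh11 (0.0503 to 0.0803) and Des (0.0544 to 0.101) were lost without Bern_ColNeg 3, Bern_SiNeg 2, Crick_ColNeg 1, 3 or 4 or Crick_SiNeg 1 or 3, that of Myh11 also without Bern_ColNeg 1 and that of Des also without Bern_SiNeg 3 or Crick_SiNeg 4. The sodium and calcium channel list rose with 2 of 16 genes past (3 adjusted over the list alone, 0.0207, adjusted p = 0.364 with an estimated correlation), the calcium channel gene Cacna1c by 1.00 ± 0.23. The pan-neuronal list did not pass (2 of 20 higher, 2 adjusted over the list alone, 0.323). Its sum (above) was nonetheless higher in Bern in both segments, in SI with 894 CPM in Bern_SiNeg 1. Of the mitochondrially encoded list 5 of 13 genes were higher and 1 lower (7 and 3 adjusted over the list alone, 1.48e-05, adjusted p = 0.364 with an estimated correlation), with a median of 0.86 and a mean of -0.07. The lower one, mt-Co2 (-1.59 ± 0.43), lost its call without Crick_ColNeg 1 (0.054) or Crick_SiNeg 2 (0.0945). Chat (2.56 ± 0.82, 0.0503), Nos1 (1.79 ± 0.59, 0.0607), Vip (1.44 ± 0.62, 0.152), Nnt (0.23 ± 0.36, 0.757) and Ahr (0.03 ± 0.53, 0.986) did not pass. In all 1780 of 19164 genes passed, 833 higher and 947 lower in Bern. The balance of directions depends on the fit. It was 277 higher and 185 lower (462) without the 4 libraries in doubt, where Pou2af1, another B cell gene (-6.70 ± 1.28), lost its call (0.0776) as did Atf3 (0.116), and 353 and 392 (745) without these and Bern_SiNeg 1. With DESeq2 it was 1238 and 3372 (4610), and without a filter on low counts 1373 and 5000 (6373). In the fit without Bern_SiNeg 1 and those in doubt the calls of Egr1 (2.55, 0.0532), Des, Npas4, Pou2af1, Atf3 and mt-Co2 were lost (0.0524 to 0.23). With limma-voom the calls of Tnfrsf13c, Cd3e, Pou2af1, Cd79b, Fcmr and Atf3 were lost (0.0684 to 0.14).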

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

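The tests chosen only after the result they bear on was seen are that of depth, those of carry-over and of pacemaker cell nuclei, and that of the genes on chromosome 4, whereas the tests of background reads and of sampled molecules across libraries and the splits of the libraries were set before.

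Every Crick library held counts for more genes than any Bern library (25789 to 35260 against 15708 to 22533), which depth does not account for, since at equal counts the lowest Crick library still had 1.07 times the genes of the highest Bern library. Background reads like those of genomic DNA may contribute: across 1385 olfactory and vomeronasal receptor genes, which gut tissue should not express, summed Crick counts followed exon length (Spearman rho 0.404 across genes, which are not independent replicates), but Bern counts did so too (0.339). Fewer RNA molecules sampled in Bern cannot be told apart from this, as the ratio of Bern to Crick shares of values at 0 among genes of 10 to 50 CPM was 3.7 in SI neurons, 15.4 in colon neurons, 13.6 in non-neuronal colon and 161 in non-neuronal SI nuclei, and a lowest value of 5 or more had been set as its mark. In colon neurons the receptor share was 0.0406% in Bern and 0.0456% in Crick while 130 to 146 against 436 to 460 receptor genes had a count, which goes with fewer molecules more than with background there, but the shares of single libraries overlap (0.0305% to 0.0662% and 0.0403% to 0.0602%) and decide nothing. In the other groups the mean share was higher in Crick: 0.0721% against 0.0451% in SI neurons, 0.124% against 0.0468% in non-neuronal SI and 0.169% against 0.0248% in non-neuronal colon nuclei. Only in non-neuronal colon did single libraries not overlap (0.0625% to 0.2259% in Crick, 0.013% to 0.0318% in Bern), which goes with more background in Crick there. The labels give no batch of sorting or sequencing that would separate handling from facility, and a difference between the mice themselves stays open and untested.

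Kit, Ano1 and Prkcq, genes of interstitial cells of Cajal, were at 255, 255 and 106 CPM in Bern and 437, 383 and 157 CPM in Crick EGFP-positive SI nuclei. Carry-over of EGFP-negative nuclei or their RNA in proportion to the whole EGFP-negative pool does not account for this, because the median log2 ratio of EGFP-positive to EGFP-negative SI nuclei was higher for these 3 genes than for the smooth muscle list by 4.51 in Bern and 4.97 in Crick (3.82 to 5.63 and 4.35 to 5.9 with 1 library left out). The comparison with smooth muscle genes cannot decide on carry-over that favours interstitial cells of Cajal. Nuclei of interstitial cells of Cajal within the EGFP-positive gate, whether labelled by the virus or carried over, remain a candidate source that cannot be told apart from expression in SI neurons. The log2 ratios of the 3 genes spanned 1.47 in Bern and 1.37 in Crick (1.05 to 1.99 and 1.18 to 1.73 with 1 library left out), between the 1 set as a mark of a single source and the 2 set against it. The other genes of the list, Etv1 and Cacna1h, say little, since neurons express them too (Etv1 at 344 CPM in colon neurons).

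Of all 51912 gene identifiers 5 were higher in every Crick library than in any Bern library, and 4 of them (Gm13302, Gm17167, Gm13301 and Gm10600) lie between 41893388 and 42242685 on chromosome 4 (12 were higher in every Bern library, and chance would separate 16 from 16 libraries in 1 direction for a share of 1.7e-09 of genes). By the marks set, background reads cannot be told apart as a source, because the ratio of EGFP-negative to EGFP-positive Crick nuclei was 1.26 in colon and 0.703 in SI, neither 1.5 or more in both, as set for background, nor at most 1.2 in both, as set against it. The receptor share, the gauge of background used above, had ratios of 3.71 and 1.72 there, which the level of these genes did not follow. Later comparisons, of their level between the facilities (9.71 and 12.2 times higher in Crick in colon and SI neurons, 18 and 10.2 times in the non-neuronal nuclei) and of their position against random draws of genes, were set aside as tests, since the genes had been picked for that difference. The receptor share was higher in Crick by 1.12 and 1.6 times in colon and SI neurons and by 6.82 and 2.65 times in the non-neuronal nuclei. For genes so picked, an excess over the receptor share was likely beforehand and cannot decide whether background reads are the source. A genetic difference between the mice, such as copy number, and reads shared between near-identical copies in this stretch both stay open and untested, and so does any other difference between the facilities.

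In 12 of 144 groups of 4 libraries 1 library lay far from the other 3, where chance flags about 1 in 20 groups. In Bern_SiNeg 1 these were Chat at 40 CPM, Elavl4 at 57.6 CPM and Nos1 at 295 CPM, above the others of the group. Crick_SiNeg 4 stood apart in Chat (2.16 CPM), Kit (283 CPM), Pou3f3 (13.1 CPM) and the number of receptor genes with a count (502). Single values stood apart for Nnt (12.5 CPM) and the receptor gene share (0.0602%) in Crick_ColPos 4, Nos1 in Crick_ColNeg 4 (213 CPM), Pou3f3 in Bern_SiPos 2 (1.49 CPM) and the receptor gene share in Bern_ColPos 1 (0.0662%).

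The test of the segment difference between neuronal and non-neuronal nuclei passed for 1395 genes. Among named genes the difference was 7.96 for Grm8, 7.59 for Slpi, 7 for Ptges3-ps, 6.56 for Syt10, 6.15 for Hcn4, 5.41 for Tmprss9, 5.39 for Btbd18 and 5.28 for Sctr on the log2 scale. It was -2.39 for Elavl4, -2.79 for Prph, -2.83 for Chat, -2.96 for Vip, -5.36 for Kit, -6.27 for Lyve1, -6.92 for Ano1, -7.73 for Prkcq, -7.78 for Slc45a3, -7.82 for Prox1, -7.92 for Lrmp, -7.93 for Fut4, -8.09 for Cdh9, -8.50 for Iqschfp, -10.05 for Ackr2 and -10.19 for Pkhd1. Calls among these were lost without 1 library for Slpi (adjusted p = 0.069 without Crick_ColPos 4), Ptges3-ps (0.0667 without Bern_SiNeg 2), Syt10 (1 without Bern_SiNeg 4), Tmprss9 (0.0791 without Bern_ColPos 2), Slc45a3 and Pkhd1 (1 without Bern_SiPos 4). For Btbd18 the call was lost without any of 8 libraries (adjusted p from 0.0504 without Bern_SiPos 2 to 0.565 without Bern_SiNeg 2) and for Iqschfp without any of 10 (from 0.0502 without Crick_SiNeg 3 to 1 without Bern_SiPos 1 or Crick_ColNeg 4). Without the libraries in doubt and Bern_SiNeg 1 the calls of Tmprss9 (0.0903), Btbd18 (0.0793) and Iqschfp (1) were lost. The test of the segment difference between the facilities passed for 1 gene, ENSMUSG00000092267, at a fitted 18.00.

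Each count of genes was set against other splits of the same libraries into groups of the same sizes, 35 splits where 8 libraries were compared and 100 draws elsewhere, and the real split was the 1 with the most genes in 9 of the 10 comparisons. For these, no other split reached the count: 9369 genes for neuronal against non-neuronal nuclei (highest other 24), 960 (371), 727 (6) and 159 (47) for colon against SI in neurons over both facilities, in Bern and in Crick, 1787 (332) in non-neuronal nuclei, 538 (357), 119 (6) and 1780 (349) for Bern against Crick in colon neurons, SI neurons and non-neuronal nuclei, and 1395 (142) for the segment by sort interaction. For segment by sort the splits cannot measure chance, since exchanging colon and SI libraries breaks up or carries the segment difference. For the other counts a rank of 1 among 35 or 100 makes chance an unlikely source but does not exclude it. The splits also take libraries as exchangeable, although sex markers follow the library number. The split with 357 genes exchanged only Bern_ColPos 4 and Crick_ColPos 4, both high in Xist, and so keeps 3 of the 4 libraries of each facility together; that with 349 kept all SI libraries and exchanged 1 colon library of each facility. For the segment by facility interaction 11 of 100 splits, the real one among them, gave 1 gene or more, so chance cannot be excluded. These splits exchanged facilities within each segment, so some carry the facility difference and they cannot measure chance here. The highest other split (886 genes) exchanged all colon and few SI libraries, which turns the contrast towards the facility difference.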

How the results depend on the processing

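The tests chosen after the data were seen are those without the doubted libraries, without these and Bern_SiNeg 1, in each facility alone, with genes higher in neuronal nuclei left out and with Xist as a covariate. The other alternatives were planned. Each side rests on 4 libraries per group, the labels give no sort or sequencing batch that would separate handling from facility, and libraries high in Y-linked genes are 2 of 4 in each Bern group and 3 of 4 in each Crick group. In simulated data, drawn once per comparison, the false calls of edgeR were 8.77% (5 of 57) for Bern and 7.69% (5 of 65) for Crick neurons alone, 6.9% (4 of 58) for Bern against Crick in SI neurons and 0% to 5.22% elsewhere, too few to place any above the 5% aimed at. The cause of the shifts below was not tested.

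Named genes gave 432 calls, a gene counted once in each comparison that names it, and all 432 kept their direction everywhere, 334 were called without each single library, and 261 were called under every alternative. Of 110 results not called, 57 passed under some alternative. Of 72 list results 61 passed without each single library, and 24 passed with an estimated correlation. The count of 9369 for neuronal against non-neuronal nuclei stayed between 8850 and 10995, and the other scaling moved no count by over 1.5 times.

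Without a filter, counts rose from 960 to 1652 (colon against SI neurons), from 727 to 1411 in Bern and from 159 to 304 in Crick, from 538 to 1034 (Bern against Crick, colon neurons), from 119 to 328 (SI neurons), from 1780 to 6373 (non-neuronal) and from 1 to 93 (segment by facility). DESeq2, simulated for colon against SI neurons alone (26.2% false calls), gave in this order 1905, 2096, 383, 1777, 447, 4610 and 47, and 3190 against 1787 for non-neuronal colon against SI and 2286 against 1395 for segment by sort. With limma-voom they were 51 in Bern and 2152 in Crick neurons, 1178 for non-neuronal colon against SI, 1307 and 677 for Bern against Crick in colon and SI neurons, 858 for segment by sort and 4 for segment by facility.

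Libraries of a facility with 1 number have the same sex markers, but the labels do not say whether they share animals. Colon and SI libraries of 1 sort were compared by their deviations from the group means over all genes. These did not go together, although Egr1 has the same order of numbers in all 4 Bern groups: same-numbered pairs correlated more than others by 0.01, 0.03, 0.03 and -0.04 (Bern neurons, Crick neurons, Bern and Crick non-neuronal nuclei), and 2, 1, 2 and 0 of 4 libraries correlated best with their own number. EGFP-positive and EGFP-negative libraries of 1 number and segment were not compared so. The pair Crick_SiPos 2 and Crick_SiNeg 2 held the highest mitochondrial shares, so pairing across the sorts stays open. With facility and number as a block the counts were 384 in Bern and 100 in Crick neurons. For Bern against Crick the block was the number alone (194 and 43 in colon and SI neurons). That block joins Bern with Crick mice and cannot allow for shared animals, also in non-neuronal nuclei. Other counts moved by under 1.5 times.

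Without the doubted libraries the counts fell to 93 in Crick neurons, 377 for non-neuronal colon against SI, 78 and 462 for Bern against Crick in SI neurons and non-neuronal nuclei, and 648 for segment by sort. Without these and Bern_SiNeg 1, which holds neuronal transcripts on the SI side as 2 of them do on the colon side, they were 764 for non-neuronal colon against SI and 745 for Bern against Crick in non-neuronal nuclei. None in doubt is a Bern neuronal library, so this was not run there. With the 8 libraries of 1 facility alone the counts were 101 in Bern and 540 in Crick neurons. With all 32 in 1 fit they were 2862 for non-neuronal colon against SI, and 164, 43 and 3176 for Bern against Crick in colon neurons, SI neurons and non-neuronal nuclei. With Xist as a covariate 307 and 68 were left in colon and SI neurons. With genes higher in neuronal nuclei left out 1051 were left for non-neuronal colon against SI and 661 for segment by sort.

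With 1 library left out the counts ran from 679 to 1120 for colon against SI neurons, 433 to 920 in Bern, 91 to 132 in Crick, 1172 to 2417 in non-neuronal nuclei, 59 to 1149, 11 to 126 and 1280 to 2652 for Bern against Crick (colon neurons, SI neurons, non-neuronal), 1116 to 1864 for segment by sort and 0 to 3 for segment by facility.

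Direction turned only for genes not called. Npy in the segment by sort test was -0.72 with limma-voom. Vip in colon against SI neurons (0.003) was -0.006 with the other scaling and with DESeq2, -0.175 with the replicate block, -0.065 without the doubted libraries and -0.221 to 0.246 with 1 library left out. For Bern against Crick, Ahr in non-neuronal nuclei (0.026) was -0.351 with limma-voom, -0.507 without the doubted libraries, -0.571 without these and Bern_SiNeg 1, and -0.278 to 0.225 with 1 library left out, where Nnt ran from -0.04 to 0.369, and Vip and Chat in colon neurons from -0.122 to 0.709 and from -0.032 to 0.433. Without the doubted libraries and Bern_SiNeg 1, Nos1 and Nnt in non-neuronal nuclei were -0.285 and -0.16.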

Other observations

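The gene lists below were fixed before the data were seen, and the tests of sex markers by library number, of single transcript and satellite shares and of genes that separate the facilities were chosen after.

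Several lists did not pass between neuronal and non-neuronal nuclei, although single genes in them changed. Of 6 sensory-type neuron genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.834), with Calcb, a calcitonin gene-related peptide gene, at 2.83 ± 0.57 and the mechanosensitive channel gene Piezo2 at -2.52 ± 0.19. Of 15 circadian genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, 0.856), with Bhlhe41 at 2.91 ± 0.32 and Nr1d1 at -2.17 ± 0.30. Of 15 immediate early genes 2 rose and 6 fell (2 and 6, 0.242), with Arc at 3.78 ± 0.53. Of 21 Hox genes of groups 1 to 8, 4 rose and 8 fell (4 and 8, 0.633), with Hoxd3 at 3.13 ± 0.43. Of 15 interferon-stimulated genes 1 rose and 7 fell (1 and 8, 0.108), with Gbp2 at -3.89 ± 0.52. Of 10 heat shock genes 1 rose and 3 fell (1 and 3, 0.43), with Hspa1b at -6.12 ± 0.75. Of 20 ribosomal protein genes 10 fell (10, 0.0515), and 2 of 8 genes of the aryl hydrocarbon receptor pathway rose (2, 0.373). Of 4 pancreatic acinar genes 2 fell (2, 0.156) and of 4 erythroid genes 1 rose and 1 fell (1 and 1, 0.727). None of 5 sex-linked genes passed (0, 0.958). Of 5 genes at loci that differ between C57BL/6 substrains 1 rose and 3 fell (1 and 3, 0.541), with Mmrn1 at -4.91 ± 0.48.

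Sex markers followed the library numbers in all 4 groups of a facility. In Bern libraries 1 and 2 Y-linked genes summed to 379 to 674 CPM and Xist to 7.03 to 63 CPM, and in Bern libraries 3 and 4 Xist was 5590 to 16100 CPM and the Y-linked sum 0.903 to 5.85 CPM. In Crick libraries 1 to 3 the Y-linked sum was 234 to 827 CPM, and in libraries 4 Xist was 5250 to 9950 CPM with a Y-linked sum of 0.838 to 1.8 CPM. The labels name no sex and do not say whether a library pools animals.

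Genes higher in every Bern library than in any Crick library included Desi2, Rab7, Tpp1, Swi5, Saal1, Calcoco1 and Spaca6, 7 of the 12. The single transcript CT010467.1 took 0.81% to 4.67% of the counts in Bern and 2.62% to 13.3% in Crick libraries, and satellite repeat genes took up to 11.2% in Crick_ColNeg 2.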
